A study of Mus musculus with 6 samples.

How the data were processed

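Back skin of 6 mouse embryos at embryonic day 15.5 was measured, 3 controls and 3 with Prmt5 deleted in the epidermis, each library from its own embryo. The labels' protocols give stranded mRNA libraries (TruSeq) sequenced on a NovaSeq as paired-end reads, with reads of 200 bp per the labels. Per the submitters' processing notes, STAR, StringTie and DESeq2 were used with the mouse build mm10, without versions, roles or order. The annotation release and the step that made the counts are not given in the sources used here.

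The authors deposited whole-number counts for 55401 gene identifiers in 6 libraries, with a DESeq2 table beside them and a Sleuth table. Totals were 45863776, 66122667 and 35667634 for control replicates 1 to 3 and 47078517, 58309148 and 45371876 for cKO replicates 1 to 3, above the number of reads the labels state. More genes held a count of 3 than a count of 2 in every library, for example 994 against 808 in control replicate 1. A count may therefore stand for less than 1 read, and floors and intervals, which cover counting error only, may be too narrow. The log2 fold changes, p-values and adjusted p-values in the authors' deposited DESeq2 table are theirs, per the file headers. A DESeq2 fit of the deposited counts matched their log2 fold changes within 0.01 for 100% of 30615 genes. The Sleuth b in the authors' deposited table is a natural log: its median ratio to the DESeq2 log2 fold change was 0.693, the natural log of 2. Sleuth p-values and q-values are as deposited, per the file headers. The deposited sheet named for a Sleuth q of 0.01 was found to hold 5362 genes with an unadjusted p under 0.01 and q up to 0.0305, and the fold-limited DESeq2 sheet to hold 1454 genes with an absolute log2 fold change over 1.

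From the counts, edgeR 4.0.16 in R 4.3.3 was used for the main test: genes were kept by filterByExpr (19227 genes), libraries were scaled by TMM, and the quasi-likelihood test compared the groups with no other term. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The biological coefficient of variation was 15.5%. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM uses TMM-scaled library sizes, and means are given with the SD over 3 libraries. For a gene at 0 in all libraries of a group, the fold was computed against a floor of 3 counts per library and is a lower bound. Gene coordinates are from the GENCODE M21 annotation on GRCm38, which held 99.5% of the identifiers.

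The 31 gene lists were fixed before the data were examined and tested with camera in limma 3.58.1 with a preset correlation of 0.01, beside camera with an estimated correlation and fry. None of the camera calls held with an estimated correlation. Of the lists' entries 543 were tested, 25 were filtered, 15 were at 0 in every library (Flg among them) and 3 symbols were not matched. Named genes followed a rule fixed before the data were examined: Prmt5, the 10 largest rises and falls among called genes with groups that do not overlap and a mean log2 CPM of at least 2, leaving out gene models without an approved-style name, up to 4 called members and the most expressed member of each list, and members wherever a count of 5 or fewer is given.

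The edgeR and camera steps were tested on simulated counts for the same 19227 genes and this comparison. The share of changed genes recovered was 74% at 1.5-fold, 88% at 2-fold, 98% at 4-fold and 100% at 16-fold, with 10 false calls among 190. Camera called the list of 25 genes that was raised and 0 of 30 lists that were not. Counts were drawn for each gene independently, so this does not test lists of correlated genes. The correlation estimated in the data was 0.448 for the spinous and 0.685 for the skeletal muscle list. Only 50 genes were changed at each fold, as many up as down, all at a log2 CPM of at least 2. The data had 6906 called genes, so these rates may not hold there. Alternatives were RLE and upper-quartile scaling, no filter, a CPM filter, DESeq2 1.42.0, limma-voom, a replicate block, other thresholds, leaving out each library, leaving out sex chromosome, erythroid and muscle genes, and the authors' adjusted p. A sex term, scaling to a pan-epithelial list and the Sleuth p limit were added after the data were seen. Python 3.11.15 with SciPy 1.17.1 made the exact permutation test and the summaries.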

Results

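Back skin of E15.5 mouse embryos was profiled by RNA sequencing in 2 groups of 3 embryos each: controls, and embryos in which Prmt5 was deleted in the epidermis (Prmt5 cKO). Prmt5 encodes a protein arginine methyltransferase that methylates histones and splicing proteins. Each library came from a different embryo and held epidermis together with dermis. The deposited gene counts summed to between 35667634 and 66122667 per library. The comparison asks which genes of the developing skin differ when the epidermis lacks Prmt5.

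Prmt5 itself (ENSMUSG00000023110.12, chromosome 14, 54507187 to 54517525, minus strand, protein coding in the GRCm38 annotation) was lower in the cKO. It measured 59.2 ± 16.6 CPM (TMM-scaled counts relative to library size; SD, n = 3) in controls and 28.2 ± 2.17 CPM (SD, n = 3) in cKO, 47.6% of control. The counts were 3094, 2656 and 2384 in the controls and 1271, 1817 and 1258 in the cKO libraries, so the groups did not overlap. The log2 fold change was -1.07 ± 0.19 (SE), with an adjusted p of 0.00292 by edgeR's quasi-likelihood test. An exact two-sided permutation test of the 6 libraries gave p = 0.1, the smallest that 3 against 3 allows. The share of Prmt5 counts that comes from dermis was not measured. With libraries scaled to a list of 15 pan-epithelial genes, a scaling chosen after the data were seen, the Prmt5 log2 fold change was -0.07 and its adjusted p by edgeR was 0.756. The median of all genes was 0.998 with that scaling, so Prmt5 still lay below the median gene. With dermis in the libraries, the lost call does not show an unchanged Prmt5 level in the epidermis.

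Genes of the differentiated epidermis fell by the largest amounts in Prmt5 cKO skin, while genes of muscle, dermis and vessels and a set of p53 targets rose by smaller amounts. The markers shared by all epithelial layers were also lower: 13 of the 15 pan-epithelial genes fell, with a median log2 fold change of -1.05. Of 19227 genes tested, 6906 changed at an adjusted p of 0.05 by edgeR's quasi-likelihood test, 3139 higher and 3767 lower in the cKO. Changes of at least 1 on the log2 scale were found for 554 higher and 1083 lower genes. The first principal component held 62.1% of the variance and separated the groups. The balance of directions depends on scaling: upper-quartile normalization gave 4514 higher and 2719 lower, and pan-epithelial scaling, which shifts the median of all genes by 0.998 on the log2 scale, gave 15554 higher and 769 lower.

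**Figure D1:**
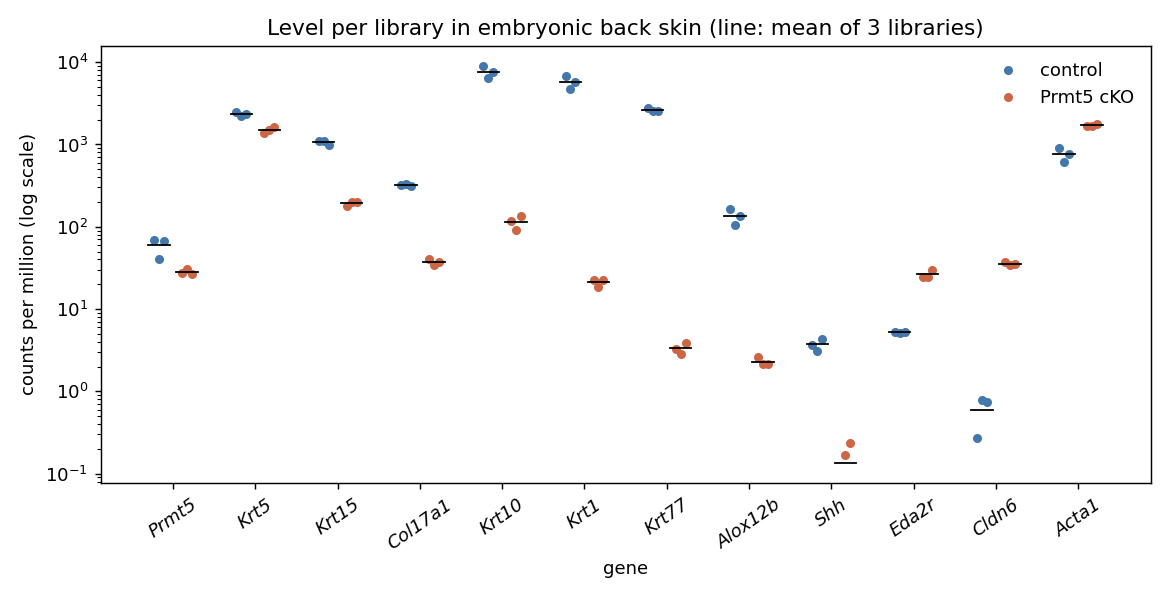
Level of 12 genes in each library, in CPM on a log axis, for 3 control and 3 Prmt5 cKO libraries, with a line at each group's mean. Krt10 averaged 7692 CPM in controls and 114.8 CPM in cKO, while Krt5 averaged 2352 and 1492 CPM.

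Suprabasal keratinocyte genes fell together. Of 19 measured spinous genes 17 fell and 1 rose (Cdkn1c, a cyclin-dependent kinase inhibitor, log2 fold change 0.49), and Notch3 did not pass (-0.25). Krt1 and Krt10, the keratin pair that marks the spinous layer, were lower by 272-fold and 67.0-fold. Krt1 went from 5771 ± 1066 to 21.3 ± 2.32 CPM (SD, n = 3 each) and Krt10 from 7692 ± 1287 to 114.8 ± 21.1 CPM. The desmosomal cadherins Dsc1 and Dsg1a fell by 4.65 and 4.33 on the log2 scale. The list median was -2.94, with an adjusted p of 8.18e-15 by camera with a preset correlation and an adjusted p of 0.258 with an estimated correlation.

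In the granular and cornified layer list 20 of 23 measured genes fell, among them the keratin Krt77 (2639 ± 146 to 3.32 ± 0.475 CPM) and the S100 fused-type protein gene Hrnr (1917 ± 579 to 3.18 ± 1.26 CPM; SD, n = 3 each). Flg2 had no counts in any cKO library and was at least 40.8-fold lower, against a floor of 3 counts per library, and Klk7, a protease of corneocyte shedding, was at least 10.9-fold lower on the same floor. Sprr2a3 and Pglyrp3 rose, with log2 fold changes of 4.08 and 0.75, and Sprr1b did not pass (-0.63). The list median was -3.18, also with the 2 genes at 0 set to their bound, with an adjusted p of 1.72e-09 by camera and an adjusted p of 0.305 with an estimated correlation. Of 18 measured barrier lipid genes 17 fell and Ugcg did not pass (-0.17). The ceramidase gene Acer1 fell by 9.55 and the lipoxygenase gene Alox12b by 5.88 on the log2 scale, and Elovl1, the most expressed member, went from 334.7 ± 34.7 to 78.7 ± 6.04 CPM (SD, n = 3 each). This list had a median of -2.68, an adjusted p of 1.87e-14 by camera and an adjusted p of 0.258 with an estimated correlation. Pglyrp3 (without cKO 3, p of 0.0587) lost its call when 1 library was left out of the edgeR fit (adjusted p).

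Cell junction and basal genes fell less. In the desmosome and tight junction list 15 of 22 genes fell, including Dsc3 (-3.55 ± 0.08, log2 fold change ± SE), Pkp1 (-2.60 ± 0.09) and Dsp (-2.06 ± 0.06). Pkp2, Cldn7, Cldn3 and Dsg3 rose, by 2.08, 1.69, 0.89 and 0.41, and Dsc2, Dsg2 and Tjp1 did not pass. Its median was -1.36, with an adjusted p of 1.99e-07 by camera and an adjusted p of 0.171 with an estimated correlation. Of 19 basal keratinocyte genes 11 fell, led by the hemidesmosome collagen Col17a1 (-3.10 ± 0.07), Krt15 (-2.46 ± 0.07) and the epithelial transcription factor gene Trp63 (-1.86 ± 0.06), while Itgb1, Ccnd1 and Dst rose. Egfr, Itga6, Itgb4 and Cdh3 did not pass. Krt5 measured 2352 ± 127 CPM in controls and 1492 ± 128 CPM in cKO (SD, n = 3 each), a log2 fold change of -0.66 that became 0.35 with pan-epithelial scaling. The basal list median was -0.71, and 0.30 with pan-epithelial scaling, with an adjusted p of 4.74e-04 by camera and an adjusted p of 0.305 with an estimated correlation. Ccnd1 (without control 1 or 2 or cKO 1 or 2, p of 0.0545 to 0.0858) and Dst (without control 2 or 3 or cKO 1, p of 0.0525 to 0.0757) lost their calls when 1 library was left out of the edgeR fit (adjusted p).

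Periderm genes went both ways. Krt8, Krt18, Krt19, Cldn6, Arhgap29, Upk1b and Muc16 rose, Krt13, Krt23, Grhl3, Upk3bl and Krt6a fell, and Krt4, Cldn4 and Krt7 did not pass. Cldn6, a claudin of embryonic epithelia, went from 0.599 ± 0.285 to 35.7 ± 1.78 CPM (SD, n = 3 each). The periderm median was 0.21, with an adjusted p of 0.66 by camera. Among stress keratins and alarmins Krt17 (1.29 ± 0.05, log2 fold change ± SE) and Il33 rose and 5 genes fell: Stfa1, Stfa3, Serpinb3a, Krt16 and Krt6a. That list was not called, with a median of -0.34 against -0.008 for all genes and an adjusted p of 0.269 by camera. With pan-epithelial scaling camera called it as lower than the other genes (median 0.66 against 0.998 for all genes, adjusted p of 4.37e-04). That scaling shifts all genes nearly alike, so the gained call does not show a larger fall against the other genes. Stfa1 and Stfa3 belong to a family of near-identical copies, so the split of reads between members is uncertain. Krt6a (without control 1 or cKO 1, p of 0.05 to 0.0509) and Krt16 (without control 1 or 3, p of 0.0581 to 0.0705) lost their calls when 1 library was left out of the edgeR fit (adjusted p).

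Genes of the hair placode fell: 14 of 22, with Shh at 3.71 ± 0.609 CPM in controls and 0.135 ± 0.121 CPM in cKO (SD, n = 3 each). The transcription factor gene Lhx2 fell by 4.67 on the log2 scale, and the Wnt inhibitor gene Dkk4 by 3.76. Krt17, Lgr5 and Nfatc1 rose, and Wnt10a, Sox9, Bmp2, Pthlh and Cdh3 did not pass. The median was -0.89, and 0.12 with pan-epithelial scaling, with an adjusted p of 1.38e-04 by camera and an adjusted p of 0.167 with an estimated correlation. In the dermal condensate list 9 of 17 genes fell, among them the Hedgehog receptor gene Ptch1 (-2.00 ± 0.06, log2 fold change ± SE), Prdm1 (-2.29 ± 0.12), Foxd1 and Sox2. Crabp1, Inhba, Fst and Ltbp1 rose, and Rspo3, Alx4, Sox18 and Tbx18 did not pass. This list was not called by camera (median -0.32 against -0.008 for all genes, adjusted p of 0.0655), while by fry its adjusted p was 7.67e-04. With pan-epithelial scaling camera called it as lower than the other genes (median 0.69 against 0.998 for all genes, adjusted p of 0.00545). That scaling shifts all genes nearly alike, so the gained call does not show a larger fall against the other genes. The basal keratinocyte and hair placode lists were also called as lower than the other genes with that scaling. Without control replicate 2 or without Prmt5 cKO replicate 1 the adjusted p of the dermal condensate list by camera was 0.0433 and 0.0465. Fst (without cKO 1 or 3, p of 0.0616 to 0.0751) and Ltbp1 (without control 1 or 2 or cKO 1 or 2, p of 0.0525 to 0.0799) lost their calls when 1 library was left out of the edgeR fit (adjusted p).

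Genes of the p53 response rose: 24 of 38 measured targets rose, 4 fell and 10 did not pass, and 25 rose and 5 fell when adjusted over the list alone, where Epha2 (-0.18) joined the falls. Cdkn1a was among the 10 that did not pass, at 186.9 CPM in controls and 202.2 CPM in cKO. Its log2 fold change was 0.11, with an adjusted p of 0.138 by edgeR. Pmaip1 did not pass either (-0.03, adjusted p of 0.873 by edgeR). Eda2r went from 5.20 ± 0.0667 to 26.5 ± 3.26 CPM and the death receptor gene Tnfrsf10b from 6.90 ± 0.932 to 22.1 ± 2.75 CPM (SD, n = 3 each). Fas had a log2 fold change of 1.58 ± 0.25 (SE). The 4 that fell were Perp, Trp73, Sesn1 and Ei24, of which Perp is also a desmosome gene and fell by 2.11. Sesn1 and Ei24, at -0.21 and -0.16, did not pass under RLE, upper-quartile normalization (-0.11 and -0.06), no filter or DESeq2, nor by the authors' deposited adjusted p (0.0604 and 0.0699). The median was 0.54, with an adjusted p of 9.82e-08 by camera and an adjusted p of 0.167 with an estimated correlation. The dermal, endothelial and muscle genes rose in the same libraries. Sesn1 (without control 1, 2 or 3 or cKO 1 or 2, p of 0.0825 to 0.133) and Ei24 (without control 1, 2 or 3 or cKO 1 or 2, p of 0.0661 to 0.176) lost their calls when 1 library was left out of the edgeR fit (adjusted p).

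Cell cycle lists were not called. Of 25 S phase genes Ccne1 rose, Pola1 and Slbp fell and 22 did not pass, with a median of 0.01 and an adjusted p of 0.892 by camera. Of 25 mitosis genes Ube2c and Cdc20 rose, 6 fell and 17 did not pass (median 0.02, adjusted p of 0.907 by camera). Mki67 had a log2 fold change of -0.18 ± 0.05 (SE), which was -0.08 and not past the threshold with upper-quartile normalization and 0.82 with pan-epithelial scaling. With that scaling camera called the S phase and DNA replication list (median 1.02, adjusted p of 0.0014) and the mitosis list (median 1.03, adjusted p of 5.71e-04) as higher. The median of all genes was 0.998 with that scaling and -0.008 without it. The scaling shifts all genes nearly alike, so these calls do not show a rise against the other genes. Pola1 (without control 2 or 3 or cKO 1 or 2, p of 0.0503 to 0.052), Slbp (without control 1, 2 or 3 or cKO 1, 2 or 3, p of 0.0671 to 0.123) and Cdc20 (without control 2 or 3 or cKO 2 or 3, p of 0.051 to 0.0697) lost their calls when 1 library was left out of the edgeR fit (adjusted p). Mki67 (without control 1 or 2, p of 0.0504 to 0.0633) lost its call when 1 library was left out of the edgeR fit (adjusted p).

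Lists of muscle, dermal fibroblast and endothelial genes were higher by camera, and not called with an estimated correlation. All 25 skeletal muscle genes rose, with a median of 0.86, including the embryonic myosin gene Myh3 (1047 ± 145 to 2005 ± 79.3 CPM) and Acta1 (759.9 ± 147 to 1702 ± 68.6 CPM; SD, n = 3 each). The adjusted p was 1.45e-14 by camera and the adjusted p was 0.305 with an estimated correlation. Of 21 dermal fibroblast genes 18 rose, among them Col1a1 (0.77 ± 0.17, log2 fold change ± SE) and Dlk1 (0.69 ± 0.11), Thy1 and Dpp4 fell, and Mfap5 did not pass. Thy1 and Dpp4 had log2 fold changes of 0.68 and 0.72 with pan-epithelial scaling. The fibroblast median was 0.47, with an adjusted p of 2.79e-06 by camera and an adjusted p of 0.448 with an estimated correlation. Of 18 endothelial genes 14 rose, such as Erg and Eng, and Cldn5, Ecscr, Flt1 and Sox17 did not pass, with a median of 0.33, an adjusted p of 5.15e-06 by camera and an adjusted p of 0.305 with an estimated correlation. Thy1 (without cKO 3, p of 0.0504) lost its call when 1 library was left out of the edgeR fit (adjusted p).

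Of 11 pericyte and smooth muscle genes 7 rose, led by the actin-binding protein genes Tagln (2.62 ± 0.20, log2 fold change ± SE) and Cnn1 (2.05 ± 0.30), Rgs5 fell, and Notch3, Myh11 and Higd1b did not pass. The median was 0.39, with an adjusted p of 0.00348 by camera and an adjusted p of 0.448 with an estimated correlation. Of 19 leukocyte genes 7 rose, such as Mrc1 and C1qc, and 12 did not pass (median 0.33, adjusted p of 3.53e-04 by camera and an adjusted p of 0.517 with an estimated correlation). Of 12 melanocyte genes Mlana, Gpnmb, Sox10 and Ednrb rose (median 0.31, adjusted p of 0.0255 by camera and an adjusted p of 0.521 with an estimated correlation). Of 25 interferon response genes 10 rose and 15 did not pass, with a median of 0.80, an adjusted p of 0.00217 by camera and an adjusted p of 0.521 with an estimated correlation. Among the genes that rose, Oasl2 went from 0.990 ± 0.0971 to 2.93 ± 0.914 CPM (SD, n = 3 each). By fry the interferon, leukocyte and melanocyte lists had adjusted p of 0.0738, 0.0666 and 0.0614. With pan-epithelial scaling the interferon response, pericyte and smooth muscle, macrophage and other leukocyte, and melanocyte lists were not called by camera (adjusted p of 0.976, 0.176, 0.089 and 0.293). Their medians were then 1.79, 1.39, 1.33 and 1.32, against 0.998 for all genes. That scaling shifts all genes nearly alike, so the lost calls do not show a smaller rise against the other genes. Rgs5 (without control 1 or 3 or cKO 1 or 2, p of 0.0564 to 0.112) and Sox10 (without control 2 or 3, p of 0.0604 to 0.0671) lost their calls when 1 library was left out of the edgeR fit (adjusted p).

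**Figure D2:**
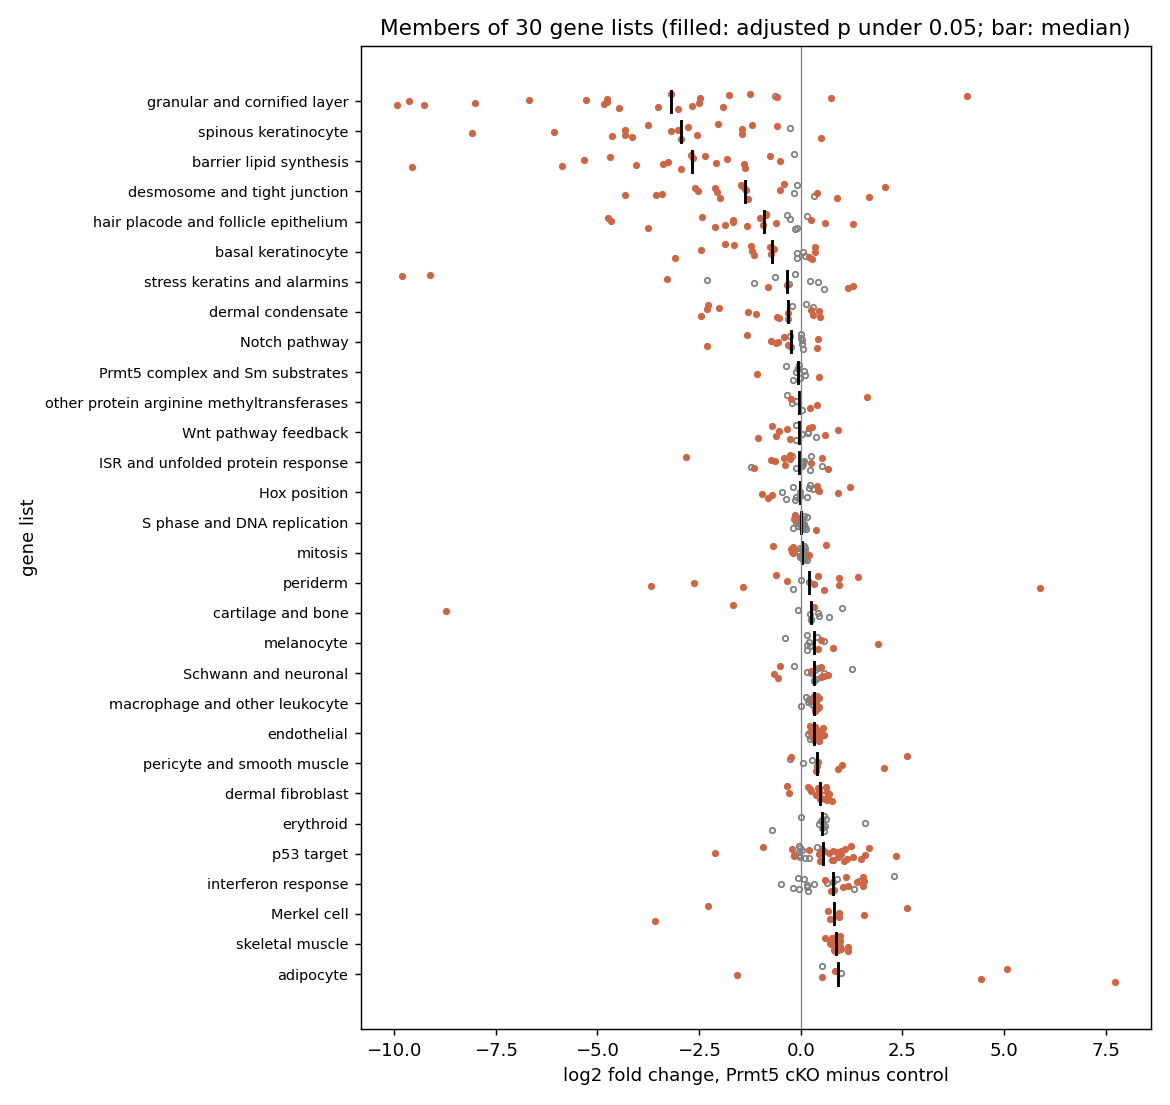
Log2 fold change, Prmt5 cKO minus control, of each measured member of 30 gene lists, filled where the adjusted p was under 0.05, with a bar at each list's median. The spinous, granular and barrier lipid medians lie at -2.94, -3.18 and -2.68 and the skeletal muscle median at 0.86.

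The other lists fixed before the data were examined were not called by camera. For the Prmt5 complex and Sm substrates Prmt5 fell and Coprs rose among 11 genes (median -0.06, and 0.95 with pan-epithelial scaling, adjusted p of 0.66). For the other protein arginine methyltransferases Prmt8, Prmt2 and Prmt1 rose, Prmt7 fell, and Prmt9, Prmt3, Prmt6 and Carm1 did not pass (median -0.05, and 0.96 with pan-epithelial scaling, adjusted p of 0.878). In the Notch pathway 7 of 16 genes fell, among them the target genes Nrarp (-1.33 ± 0.07, log2 fold change ± SE) and Hes5, and Mfng and Dll4 rose (median -0.25, and 0.76 with pan-epithelial scaling, adjusted p of 0.0556). The Notch adjusted p by camera was 0.0473 without control replicate 3 and 0.0382 without Prmt5 cKO replicate 1. By fry the Notch list had an adjusted p of 0.00107 with all libraries. For Wnt feedback 6 of 16 genes fell, such as Dkk1 and Lef1, and Sp5, Lgr5, Twist2 and Twist1 rose (median -0.04, and 0.97 with pan-epithelial scaling, adjusted p of 0.66). Coprs (without control 1 or 3 or cKO 2 or 3, p of 0.0626 to 0.0984), Prmt8 (without control 1 or 2 or cKO 1 or 3, p of 0.0508 to 0.12) and Prmt1 (without control 3 or cKO 2 or 3, p of 0.0542 to 0.0592) lost their calls when 1 library was left out of the edgeR fit (adjusted p). Prmt7 (without control 1 or 2 or cKO 1 or 3, p of 0.0873 to 0.121), Mfng (without cKO 2 or 3, p of 0.0563 to 0.0613) and Dll4 (without control 2 or 3 or cKO 1, p of 0.0691 to 0.0743) lost their calls when 1 library was left out of the edgeR fit (adjusted p). Sp5 (without control 1 or 3 or cKO 2, p of 0.0502 to 0.0691) and Twist1 (without control 1 or 3 or cKO 1 or 2, p of 0.0581 to 0.0956) lost their calls when 1 library was left out of the edgeR fit (adjusted p).

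In the integrated stress and unfolded protein response list 8 of 22 genes fell, led by the cystine transporter gene Slc7a11 (-2.83 ± 0.30, log2 fold change ± SE), and Atf3, Sesn2 and Mthfd2 rose (median -0.04, and 0.97 with pan-epithelial scaling, adjusted p of 0.528 by camera). Of 8 Merkel cell genes 6 rose, and Sox2 and Atoh1 fell (median 0.82, adjusted p of 0.0656). Atoh1 had 9 counts in Prmt5 cKO replicate 2 and none in the other cKO libraries. Its fitted log2 fold change of -3.58 was -8.07 without that library, a value set against counts of 0. Of 18 Schwann and neuronal genes Gfra3, Foxd3, Sox10, Fabp7 and Ngfr rose and Mbp, Erbb3 and Stmn2 fell (median 0.33, adjusted p of 0.196). Of 11 cartilage and bone genes Runx2 rose and Ibsp (0 counts in cKO, at least 17.6-fold lower against the floor of 3 counts per library) and Sp7 fell (median 0.24, adjusted p of 0.658). Of 19 Hox genes Hoxd3, Hoxb9, Hoxd8, Hoxc5 and Hoxc6 rose and Hoxb8, Hoxa7 and Hoxb7 fell (median -0.01, and 0.99 with pan-epithelial scaling, adjusted p of 0.716). None of the 12 erythroid genes passed in edgeR's test (median 0.53, adjusted p of 0.0581 by camera); without Prmt5 cKO replicate 1 and without control replicate 1 that p was 0.00119 and 0.0242. The sex chromosome genes Xist, Ddx3y, Eif2s3y, Kdm5d and Uty did not pass (list adjusted p of 0.864 by camera), and 1 control and 2 cKO libraries had the counts of females. With pan-epithelial scaling camera called the sex chromosome check list as lower than the other genes (adjusted p of 4.39e-04). That scaling shifts all genes nearly alike, so the call does not show a changed place among them. Sesn2 (without cKO 2 or 3, p of 0.0527 to 0.0663), Mthfd2 (without control 2 or 3 or cKO 1 or 3, p of 0.0574 to 0.0797) and Atoh1 (without control 2, p of 0.0524) lost their calls when 1 library was left out of the edgeR fit (adjusted p). Krt20 (without control 2 or 3 or cKO 1, 2 or 3, p of 0.055 to 0.0757) and Rab3c (without control 3 or cKO 1 or 2, p of 0.0534 to 0.0577), which are among the Merkel cell genes that rose, lost their calls in the same way. Foxd3 (without control 1 or 3 or cKO 1, 2 or 3, p of 0.051 to 0.114), Fabp7 (without control 2 or 3 or cKO 1, 2 or 3, p of 0.0576 to 0.0983) and Ngfr (without control 3 or cKO 3, p of 0.0512 to 0.0513) lost their calls when 1 library was left out of the edgeR fit (adjusted p). Runx2 (without cKO 1 or 3, p of 0.0555 to 0.0671), Hoxc5 (without control 1 or 3 or cKO 1 or 3, p of 0.0521 to 0.0829) and Hoxc6 (without control 1 or 3 or cKO 1 or 3, p of 0.0531 to 0.106) lost their calls when 1 library was left out of the edgeR fit (adjusted p).

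For some lists the counts differed when adjusted over the list alone. On that adjustment 21 granular genes fell (20 over all genes tested), 18 barrier lipid genes (17 over all), 15 hair placode genes (14 over all) and 11 dermal condensate genes (9 over all). Adjusted over the list alone, 19 fibroblast genes rose (18 over all genes tested), 17 endothelial (14 over all), 14 interferon response (10 over all), 10 leukocyte (7 over all), 7 Schwann and neuronal (5 over all), 6 Hox (5 over all) and 6 adipocyte genes (5 over all), and Kit rose beside the melanocyte genes Mlana, Gpnmb, Sox10 and Ednrb. On the same adjustment Dsc2, Rspo3, Dkk3 and Nos2 rose as well, Prmt3, Prmt9 and Hoxa5 fell, as did 6 stress keratins and alarmins (5 over all), and Coprs and Slbp did not pass. The counts of falls were the same on both adjustments for the spinous (17), basal (11), desmosome (15), Notch (7) and mitosis (6) lists, as were those of rises for the muscle (25), pericyte (7) and Merkel (6) lists.

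Of 8 measured adipocyte genes, Adipoq, Plin4, Car3, Lpl and Cd36 rose, Cebpa fell, and Fabp4 and Pparg did not pass (median 0.92, adjusted p of 0.128 by camera). The adjusted p of the adipocyte list by camera was 0.0231 without Prmt5 cKO replicate 1. Car3 had 54957 counts in Prmt5 cKO replicate 2, against 2129 and 8873 in the other cKO libraries and 787, 730 and 899 in controls. Gpd1, with a log2 fold change of 6.47 ± 1.57 (SE), had 12437 counts in that library and 74 and 1448 in the other cKO libraries. Without Prmt5 cKO replicate 2 the log2 fold changes of Car3, Gpd1 and Plin4 were 2.71, 4.11 and 3.12. Car3, Gpd1, Adipoq and Plin4 did not pass with a sex term, chosen after the data were seen (adjusted p of 0.0702, 0.0688, 0.0839 and 0.101), nor by limma-voom (0.0622, 0.378, 0.555 and 0.15). Adipoq (without control 1, 2 or 3 or cKO 2, p of 0.0515 to 0.0666), Plin4 (without control 2, p of 0.0534) and Gpd1 (without control 2, p of 0.0519) lost their calls when 1 library was left out of the edgeR fit (adjusted p).

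The falls picked by the fixed rule, which sorts fitted values, were Cyp2b19, Lce3f, C6, Oas1f and Skint2, each at 0 in all cKO libraries, and Krtap13, Cstdc6, Krt77, Acer1 and Skint7. The folds of the genes at 0 are lower bounds, so their place among the others is not settled. Cyp2b19, a cytochrome P450 gene of keratinocytes, was at least 458-fold lower, and the complement gene C6 at least 243-fold lower. Skint7 had 2 counts in the cKO libraries together and was 721-fold lower (95% counting interval 199.6 to 5955). Among called genes with groups that do not overlap, a mean log2 CPM of at least 2 and an approved-style name, the largest rises were Pcdhga10, Gpd1, Cldn6, Gemin4, Car3, Sprr2a3, H2-Eb1, Sprr2a2, Sprr2a1 and Abcb1b. The class II gene H2-Eb1 went from 2.36 ± 0.563 to 33.5 ± 6.13 CPM (SD, n = 3 each), while H2-Aa, H2-Ab1 and Cd74, named after their values were seen, did not pass. Pcdhga10 and Gemin4 overlap other annotated loci and had a q of 0.503 and 0.455 in the authors' deposited Sleuth table, so their assignment is uncertain, as is that of the near-identical Sprr2a1, Sprr2a2 and Sprr2a3. Gemin4 had 2229 counts in Prmt5 cKO replicate 2 and 21 and 25 in the other cKO libraries, and its log2 fold change was 0.70 without that library. Gemin4 (without control 1, 2 or 3 or cKO 2, p of 0.108 to 0.325) lost its call when 1 library was left out of the edgeR fit (adjusted p).

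Some of the genes named here as changed did not pass an adjusted p of 0.05 in other fits. With upper-quartile normalization these were Prmt7, Krt6a, Sesn1, Ei24, Pola1, Slbp, Mki67 and Rgs5. With RLE these were Sesn1, Ei24 and Slbp. With no filter these were Prmt7, Sesn1, Ei24, Slbp, Foxd3 and Fabp7. With DESeq2 these were Sesn1, Ei24, Slbp and Fabp7. By limma-voom these were Gpd1, Gemin4, Car3, Krtap13, Adipoq and Plin4. With the replicate block these were Gemin4, Coprs, Ccnd1, Ltbp1, Ei24, Slbp, Foxd3, Fabp7, Rab3c, Krt20, Runx2, Hoxc5 and Hoxc6. With the sex term these were Gpd1, Gemin4, Car3, Coprs, Ei24, Slbp, Fabp7, Adipoq, Plin4, Atoh1 and Krt20. With pan-epithelial scaling, where the median of all genes was 0.998, these were Prmt5, Krt16, Trp73, Dkk1, Cebpa, Hoxb8 and Hoxb7. By the authors' deposited adjusted p these were Sesn1, Ei24, Slbp and Fabp7. Gemin4 has no adjusted p in the DESeq2 fit or in the authors' deposited table, so it was not called there. The filter on CPM of at least 1 in 3 libraries left Adipoq, Atoh1, Gemin4, Hes5, Ibsp, Klk7, Krt20, Plin4, Prmt8 and Rab3c untested.

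The authors' deposited DESeq2 table lists 5340 genes at an adjusted p under 0.01, 2493 higher and 2847 lower in the cKO. At 0.05 the authors' deposited table has 6837 genes, of which 6421 were also called by edgeR, all 6421 with the same sign. The authors' deposited Sleuth table has 4563 genes at a q under 0.01, and 3980 genes passed 0.01 in both deposited tables, all 3980 with the same sign. Genes past an adjusted p of 0.01 in the authors' deposited DESeq2 table with a change of over 1 on the log2 scale were looked up in Sleuth. Of those that rose, 288 of 378 listed by Sleuth (76.2%) passed a Sleuth q of 0.01 in that direction. Of those that fell, 835 of 875 (95.4%) did. The difference between these shares was not tested.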

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

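The sex term, the pan-epithelial scaling and the Sleuth p limit were chosen after the data were seen. The number of genes changed stayed within 1.5 times of 6906 under 17 of the 20 alternatives. It was 4398 at an adjusted p of 0.01, 1637 with a log2 fold change of at least 1 as well, and 16323 with pan-epithelial scaling. Genes higher were 1825, 554 and 15554 and genes lower 2573, 1083 and 769 under the same settings, and the thresholds' own construction shows the cause of the first pair. Leaving out 1 library gave 5713 to 5912 changed genes, 2477 to 2803 higher and 3024 to 3300 lower. Prmt5 kept its call in each alternative but pan-epithelial scaling, where it was -0.07, and it lay between -1.28 and -0.91 when 1 library was left out. Camera called 14 lists and 0 with an estimated correlation, the cause of which was not tested. Correlation between genes cannot be the whole cause. The hair placode list had an estimated correlation of -0.028, yet its unadjusted p by camera went from 4.01e-05 to 0.0107. In the simulation the raised list of independent genes went from an adjusted p by camera of 3.49e-80 to 8.72e-04. Fry called 15 lists, among them the dermal condensate, Notch, ISR and Merkel lists (adjusted p of 7.67e-04, 0.00107, 0.0295 and 0.0247). It did not call the interferon, leukocyte and melanocyte lists. Leaving out 1 library gave 14 to 18 lists by camera. The genes past 0.01 in both deposited tables fell from 3980 to 720 with the fold limits, by their construction. With the replicate number as a block, 6098 genes changed and Prmt5 was at -1.03 with an adjusted p of 0.0115. Samples with the same number did not deviate together (correlations across genes of -0.068, -0.04 and -0.056). These values gave no sign that the numbers pair the embryos. They cannot exclude it, with 3 libraries per group and same-number libraries that differ in sex by their counts. Of 175 named genes that were called, 147 kept their call without Prmt5 cKO replicate 1, 161 with the sex term, 172 with RLE, 165 with upper-quartile scaling and 169 with DESeq2. At an adjusted p of 0.01 it was 123, with a log2 fold change of at least 1 it was 86, and 144 kept call and sign with pan-epithelial scaling. In every setting 70 of the 175 stayed the same. No value was given for Gemin4 by DESeq2 and the authors' adjusted p, for low genes by the CPM filter, or for genes left out by design. Alternatives for normalized values (pseudocount, filter on low values) were not run, since the files hold counts. With pan-epithelial scaling these named genes turned from negative to positive log2 fold changes: Prmt7 0.77, Prmt9 0.68, Prmt3 0.80, Prmt6 0.88, Krt5 0.35, Itga6 0.92, Cdh3 0.92, Notch3 0.75, Sprr1b 0.38, Ugcg 0.83, Upk3bl 0.39, Krt6a 0.66, Cldn4 0.81, Krt7 1.01, Krt16 0.21, Dsg2 0.84, Tjp1 0.91, Wnt10a 0.68, Bmp2 0.86, Pthlh 0.74, Alx4 0.70, Sox18 0.80, Trp73 0.08, Sesn1 0.79, Ei24 0.85, Pola1 0.83, Slbp 0.87, Rrm1 0.99, Ttk 0.33, Nusap1 0.77, Kif11 0.80, Mki67 0.82, Lfng 0.27, Jag1 0.39, Wif1 0.30, Lef1 0.41, Apcdd1 0.89, Psat1 0.29, Thy1 0.68, Dpp4 0.72, Rgs5 0.77, Mbp 0.34, Erbb3 0.44, Stmn2 0.49, Hoxb8 0.05, Hoxa7 0.19, Hoxb7 0.30, Epha2 0.83 and Hoxa5 0.66. So did the medians of the Prmt5 complex and Sm substrates list 0.95, the other protein arginine methyltransferases list 0.96, the basal keratinocyte list 0.30, the stress keratins and alarmins list 0.66, the hair placode and follicle epithelium list 0.12, the dermal condensate list 0.69, the Notch pathway list 0.76, the Wnt pathway feedback list 0.97, the ISR and unfolded protein response list 0.97 and the Hox position list 0.99. The construction shows the cause, since this scaling shifts the median of all genes by 0.998. Values near 0 also turned sign in other settings, and the cause was not tested: Itga6 0.01, Cdh3 0.01, Krt7 0.10 and Rrm1 0.09 (upper-quartile normalization), Krt7 0.01, Rrm1 0.01 and the Hox position list 0.00 (RLE normalization), Krt7 0.00 (no filter), Krt7 0.01 and the ISR and unfolded protein response list 0.04 (CPM of at least 1 in 3 libraries), Krt7 0.01 and Rrm1 0.01 (DESeq2), Krt7 0.00 (limma-voom), Krt7 0.00 (without sex chromosome, erythroid and muscle genes), Krt7 0.01 and Rrm1 0.01 (authors' deposited adjusted p 0.05), Krt7 0.01 and Rrm1 0.01 (authors' deposited adjusted p 0.01), Higd1b -0.05, Xist -0.03, the S phase and DNA replication list -0.01 and the Hox position list 0.05 (sex term). Over the fits that left out 1 library the sign turned, with these ranges, for Carm1 (0.00 to 0.07), Krt7 (-0.04 to 0.08), Pthlh (-0.44 to 0.04), Rrm1 (-0.07 to 0.04), Notch1 (-0.03 to 0.06), Higd1b (-0.29 to 0.41), the other protein arginine methyltransferases list (-0.07 to 0.00), the S phase and DNA replication list (-0.04 to 0.03), the mitosis list (-0.01 to 0.07), the Wnt pathway feedback list (-0.07 to 0.02), the ISR and unfolded protein response list (-0.08 to 0.02), the Hox position list (0.01 to 0.14).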

Other observations

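The gene families, the tests of the muscle pattern, the globin test and the p53 test against dermal genes were chosen after the data were seen. The family p-values are adjusted over 58 tests. They come from a hypergeometric test that treats genes as independent, so they may be too small where members of a family vary together. Among 34 tested genes of the epidermal differentiation complex, between S100a9 and S100a10 on chromosome 3, 17 fell and 5 rose (adjusted hypergeometric p of 4.71e-04 for falls). All 7 tested Skint genes, which encode butyrophilin-like proteins of skin and thymus, fell, with an adjusted p of 1.28e-04, as did all 5 connexin genes of the Gjb group, 7 of 8 kallikrein genes and 14 of 20 Serpinb genes. Members of the Skint, Serpinb and kallikrein families resemble each other, so the split of counts within a family is uncertain. The falls in these families were as many under RLE and upper-quartile scaling. With pan-epithelial scaling 15 genes of the epidermal differentiation complex fell and 13 rose, 12 Serpinb genes fell and 5 rose, and falls numbered 7 for Skint, 7 for kallikrein and 4 for Gjb genes.

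Collagen genes rose in 27 of 43 and fell in 4 (adjusted hypergeometric p of 2.59e-10). With upper-quartile scaling 29 rose and 3 fell, and with pan-epithelial scaling 41 rose and 1 fell. Of 82 cytosolic ribosomal protein genes 67 fell, with a median log2 fold change of -0.23, but 33 fell with upper-quartile scaling, 44 without control replicate 1 and 0 with pan-epithelial scaling, where the median was 0.78. Of 156 genes within 5 Mb of Prmt5 on chromosome 14, 26 rose and 24 fell, with an adjusted p of 1 each way. Other splits of the 6 libraries into 3 and 3 called at most 7 genes, against 6906 for the real split, which was the 1 split of 10 with as many. With 10 splits the share cannot go under 0.05. Each other split mixes control and cKO libraries in both of its groups, which widens the spread within them. The low counts of those splits therefore do not measure false calls in the real split. The split with 7 genes parts the female from the male libraries.

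The fall of spinous, granular and barrier lipid genes was weighed first. A smaller share of epidermis in the skin piece would lower all epithelial genes alike. After the pan-epithelial median of -1.05 was set to 0, the median of the 60 members was still -1.89 (95% interval -2.59 to -1.26, bootstrap over member genes). The interval does not measure the spread between embryos. The 15 pan-epithelial genes themselves ranged from -2.27 to 0.70, so the size of the correction is uncertain. With their median as the correction, the values argue against a smaller share as the whole cause. The fall of 13 of 15 pan-epithelial genes leaves a smaller share open as a part. Whole embryos at an earlier stage cannot be told apart from the deletion, since the log2 ratio of embryonic to adult beta globin counts was 0.17 higher in cKO with the groups overlapping. A block of keratinocyte differentiation was not tested and is left open beside these.

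The rise of skeletal muscle genes was larger than that of the dermis. The muscle list rose by 0.88 and the dermal fibroblast list by 0.42, a difference of 0.46 ± 0.08 (SE over libraries) with no overlap of the groups, which argues against a smaller share of epidermis raising all other cell types alike. The rise of all 25 measured muscle genes is the pattern itself, so more muscle tissue in the skin piece, by dissection or by the deletion, stays open.

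The rise of p53 target genes was set against the same shift. Of 38 targets, 11 rose above 0.97, the 95th percentile of 50 dermal, endothelial and pericyte members. By chance 1.9 would (exact one-sided binomial p of 1.67e-06, which treats the targets as independent). These 11 thus rose more than most genes of those cell types. Skeletal muscle genes, with a median of 0.86, were not in the reference. The test therefore cannot decide about a shift in cell types that includes muscle. Ak1, which muscle also expresses, is among the 11. The lowest list median without 1 cKO library was 0.54, against 0.54 in all libraries, so no single cKO library carried the rise. A p53 response to the deletion is a candidate explanation that these libraries cannot separate from an indirect change in cell types.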
